A study of Candida albicans with 12 samples.

How the data were processed

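RNA of Candida albicans SC5314, a wild-type laboratory strain of this yeast, was sequenced from untreated cells and from cells treated with NFAP2, an antifungal protein of the mould Neosartorya (Aspergillus) fischeri. Per the labels' protocols, RNA was purified with a plant RNA miniprep kit and libraries were made with the NEBNext Ultra II Directional kit, which keeps the strand of the RNA. Each of the 12 deposited files holds raw total counts per gene, per the file headers, with no scaling. The aligner, the counting program, the genome build and how strand was handled in counting are not given in the sources used here, so no coordinates are reported and reads of overlapping or antisense genes cannot be assigned with certainty. The same holds for reads shared within families of similar genes, such as the HGT, GIT, PHO and histone genes. The 6048 gene identifiers of the files all matched the RefSeq gene table of assembly ASM18296v3, which was used for names alone. It gave a symbol to 2826 genes, and 3222 had a systematic name only.

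The 12 files form 6 pairs that share treatment, batch number and library name apart from a last number. Within a pair the counts differed by a chi-square of 1.00 to 1.055 per degree of freedom over genes with at least 10 counts (p between 0.00195 and 0.501 in a chi-square test over genes, which are not replicates). The same quantity between cultures of one group was 3.47 to 34.88. The paired files thus differed by about the sampling noise. They were summed and counted as 1 sample, here called a culture, which leaves 3 untreated and 3 NFAP2-treated cultures. Counts per file ran from 749433 to 2104593, and counts per culture from 2454001 to 2854026. A gene had a median of 147 counts per culture, and a gene with 100 counts has a counting error of about 10.0%. The reads carry no molecular identifiers in the sources used here, so intervals made from counts cover counting error only.

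Genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 on the 3 against 3 cultures, after filterByExpr and with TMM factors, and adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. TMM factors were 0.935 to 0.953 in untreated and 1.042 to 1.069 in treated cultures. CPM values, the counts scaled by library size, are TMM-scaled, and each log2 fold change is the fitted value of treated minus untreated cells. Its standard error (SE) was derived as the absolute log2 fold change divided by the square root of the F statistic. This SE is approximate and may be too small where a group has few counts, as for TNA1 with 4, 7 and 5 counts in the treated cultures. A total of 30 gene lists was written from symbols, and 29 with at least 5 tested genes were tested with camera of limma 3.58.1 at its preset correlation between genes of 0.01, adjusted over the 29 lists. The list of mitochondrially encoded genes had 0 members in the files and was not tested. Of 856 symbols written, 776 were found. Camera was run again with a correlation estimated from the data for each list.

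Groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 largest rises and the 10 largest falls among genes with a symbol, an adjusted p under 0.05, a mean of at least 10 CPM and no overlap between the groups. It also took, per list and direction, up to 3 members past the threshold with at least 10 CPM and the largest change, or up to 2 with the smallest p where no member passed. Other genes are said to have been chosen after their values were seen.

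The alternatives were the batch number as a replicate block, other scaling factors (RLE, or total counts alone), no or a stricter low-count filter, the first or the second count file alone, the 12 files as separate samples, each culture left out in turn, limma-voom, and DESeq2 1.42.0. The labels call the number a batch, so it pairs cultures by label. The title of the treated culture of batch 3 carries another number than its batch label, so the pairing of that batch is in doubt. Cultures that share a number did not deviate together from their group means: the correlations across genes were -0.339, 0.064 and -0.365 for batches 1, 2 and 3. The highest value among the other pairs was 0.398, for untreated culture 1 with treated culture 3.

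The tests were checked on simulated counts with 50 genes changed at each fold size, drawn for this comparison of 3 against 3 cultures with 5656 genes tested. The edgeR test recovered 18% of genes changed 1.5-fold, 78% at 2-fold, 98% at 4-fold and 100% at 8-fold, with 6 false calls among 153. Far fewer genes changed in the simulation than in the real data. The adjusted threshold was therefore stricter in the simulation, and these shares do not carry over to the real comparison. Camera called 5 of 5 raised lists and 0 of 20 unchanged ones, both with the preset and with the estimated correlation, in lists whose genes were drawn independently.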

Results

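Gene expression was measured by RNA sequencing in 3 untreated and 3 NFAP2-treated cultures of C. albicans SC5314. Cells were shaken at 30 °C in 40 ml of a low-ionic-strength medium with 0.5% glucose, 0.25% yeast extract and 0.0125% peptone. Per the labels' growth protocol, the sole source of the times, treated cells received 15 µg/ml NFAP2 and were incubated for 6 h, and untreated cells were incubated for 2 h. If the protocol gives the times correctly, treatment and time differ together in this design, and each difference below is between treated cells at 6 h and untreated cells at 2 h. Each culture had 2 count files, which differed by about the sampling noise and were counted as 1 sample. The untreated cultures 1 to 3 had 2454001, 2854026 and 2456251 counts, and the treated cultures 1 to 3 had 2791524, 2653624 and 2741761. The 10 most abundant genes took 10.25%, 10.23% and 10.56% of the counts in untreated cultures and 7.13%, 7.31% and 7.59% in treated ones.

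The comparison asked how the transcriptome of cells exposed to NFAP2 differed from that of untreated cells. In the treated cultures, 28 of 42 cell wall genes, 9 of 10 histone genes and 23 of 39 cell cycle genes rose, while 47 of 54 amino acid synthesis genes, 16 of 21 glycolysis genes and 15 of 21 heat shock protein genes fell. Of 5663 genes tested, 2483 changed (43.8%), 1219 upward and 1264 downward, and 1293 changed at least 2-fold, 652 upward and 641 downward. The groups did not overlap in 3265 genes (57.7%), where chance gives 10% for 3 against 3. With total-count scaling, which raised the median log2 fold change of all genes by 0.165, the calls were 1614 upward and 1004 downward.

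The largest rises included several cell surface genes. RBR1, a cell wall protein gene needed for filamentous growth at acidic pH, had 5 counts over the untreated cultures and 1076 over the treated ones, a ratio of 182 with a 95% exact counting interval of 77.7 to 562. PCL1, a cyclin of the Pho85 kinase, had 5 against 572 counts, a ratio of 96.7 with an interval of 41.2 to 299. With so few untreated counts, the fitted log2 fold change of PCL1 was 5.78 with the first count file alone and 9.04 with the second. PGA23 and PGA6, which encode putative GPI-anchored surface proteins, rose from 8.88 ± 5.21 to 636 ± 246 CPM and from 47.7 ± 13.3 to 988 ± 142 CPM (SD, n = 3 per group). Their log2 fold changes were 6.18 (SE 0.49, adjusted p = 0.000106) and 4.37 (SE 0.24, adjusted p = 3.35e-05). CSH1, an aldo-keto reductase family gene linked to surface hydrophobicity, rose by 5.15 (SE 0.45), RTA4 by 4.52 (SE 0.40), DAG7 by 4.09 (SE 0.34), the ferric reductase gene CFL5 by 3.95 (SE 0.63) and MRV1 by 3.94 (SE 0.50). The white-phase gene WH11 rose by 4.13 with a wide error (SE 0.98, adjusted p = 0.0112). Untreated culture 1 held more of the transcripts of several of these genes: without it the values were 6.02 for CSH1, 4.57 for MRV1 and 6.09 for WH11, and WH11 was at 3.36 without treated culture 3 and 5.01 with limma-voom.

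TNA1, a putative nicotinic acid transporter gene, fell from 654 ± 112 to 1.86 ± 0.609 CPM (SD, n = 3 per group), a log2 fold change of -8.43 (SE 0.27, adjusted p = 9.09e-06). The acid phosphatase gene PHO100 was at -7.12 (SE 0.52), and GIT4 and GIT1, of the glycerophosphodiester transporter family, were at -6.19 (SE 0.57) and -4.80 (SE 0.44). LEU1 of leucine synthesis fell from 3572 ± 335 to 112 ± 23.4 CPM (log2 -5.00, SE 0.21), the oligopeptide transporter gene OPT3 was at -4.74 (SE 0.24), and YHB1, a nitric oxide dioxygenase gene, fell from 2585 ± 355 to 99.1 ± 32.2 CPM (-4.70, SE 0.27). The sugar transporter genes HGT1 and HGT2 were at -6.13 (SE 1.03) and -5.22 (SE 0.62), and the sodium pump gene ENA2 at -4.95 (SE 1.07). These last 3 genes were highest in untreated culture 1, and without it their values were -4.38, -4.36 and -3.04, with the adjusted p still under 0.05. HGT1 and ENA2 were at -5.31 and -4.17 with batch as a block and at -5.29 and -4.13 with limma-voom, and GIT1 was at -5.51 without treated culture 3.

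**Figure D1:**
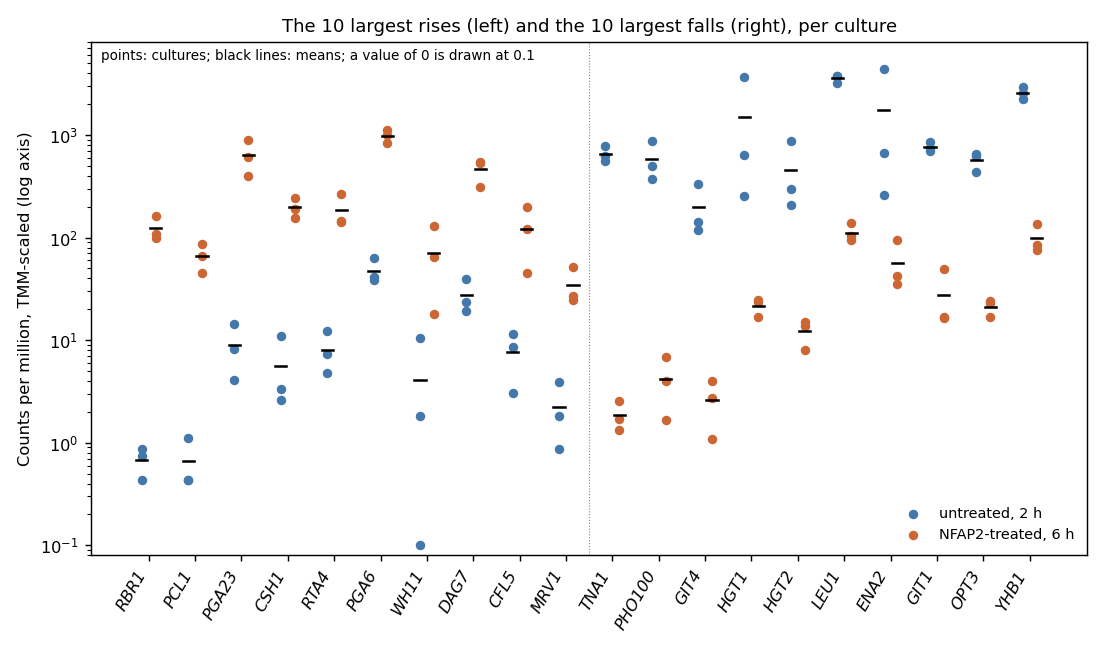
TMM-scaled CPM (log axis) of the 10 genes with the largest rises (left of the dotted line) and the 10 with the largest falls (right) in each of the 3 untreated (blue, 2 h) and 3 NFAP2-treated (orange, 6 h) cultures; black lines are group means. TNA1 went from a mean of 654 to 1.86, while HGT1, HGT2 and ENA2 spread widely over the untreated cultures.

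Most cell wall genes rose. Of 42 tested genes of cell wall synthesis and remodelling, 28 rose, 3 fell and 11 did not pass (28 and 4 adjusted over the list alone), with a median log2 fold change of 1.22 (camera adjusted p = 6.27e-10; adjusted p = 0.129 with an estimated correlation). CRH11, which encodes a glycosidase that crosslinks chitin and glucan, rose from 90.6 ± 25.1 to 1304 ± 386 CPM (log2 3.85, SE 0.30), and the GPI-anchored protein gene ECM331 from 78.6 ± 20.6 to 988 ± 141 CPM (3.65, SE 0.23). The 3 falls were RHD3 (-2.83, SE 0.44), the CRH11 relative CRH12 (-1.99, SE 0.18) and GSL1 of the glucan synthase family (-0.45, SE 0.15, adjusted p = 0.0417), whose call was lost with batch as a block, total-count scaling, DESeq2 or the second count file alone. GSL1 also lost its call without treated culture 1, 2 or 3 and without untreated culture 2 or 3, with values from -0.53 to -0.38.

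Lipid genes had smaller median changes. Of 28 phospholipid and sphingolipid genes, 14 rose and 2 fell (15 and 2 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 0.0032; adjusted p = 0.238 with an estimated correlation). CHO1, the phosphatidylserine synthase gene, rose from 53.9 ± 10.9 to 293 ± 17.1 CPM (log2 2.44, SE 0.18), and the ceramide synthase gene LAC1 rose by 2.22 (SE 0.25). Of 24 genes of the ergosterol and mevalonate pathway, 12 rose and 2 fell, the same counts as adjusted over the list alone, with a median of 0.50 (camera adjusted p = 0.0425; adjusted p = 0.421 with an estimated correlation). ERG2 rose by 1.59 (SE 0.20) and ERG25 by 1.32 (SE 0.21), while the squalene epoxidase gene ERG1 fell by 0.93 (SE 0.16). The sterol list lost its call with batch as a block (0.0564, with 8 genes changed), without untreated culture 1 (0.0502) or 2 (0.0547, 7 genes), and without treated culture 2 (0.0823, 8 genes) or 3 (0.0842). It was also lost with the stricter low-count filter (0.0502) and with the second count file alone (0.0599).

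Most histone and cell cycle genes rose. Of 10 histone genes, 9 rose and 1 fell, also adjusted over the list alone, with a median of 1.61 (camera adjusted p = 5e-08; adjusted p = 0.238 with an estimated correlation). The H4 gene HHF22 rose from 176 ± 5.55 to 692 ± 42.7 CPM (log2 1.98, SE 0.13) and the H3 gene HHT21 from 334 ± 35.3 to 1256 ± 36.8 CPM (1.91, SE 0.14). The gene that fell was HHT1 (-0.55, SE 0.15), whose call was lost with batch as a block, with total-count scaling, with the first count file alone and without treated culture 1, 2 or 3 (-0.58 to -0.54). Of 39 genes of the cell cycle and DNA replication, 23 rose and 2 fell (24 and 2 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 3.68e-06; adjusted p = 0.421 with an estimated correlation). The G1 cyclin gene CCN1 rose by 3.48 (SE 0.24) and the Pho85 cyclin gene PCL2 by 3.70 (SE 0.38), while PCL5, another cyclin of that kinase, fell by 2.06 (SE 0.17) and the transcription factor gene MBP1 by 0.63 (SE 0.12).

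Ribosome biogenesis genes rose in part. Of 63 members, 26 rose and 0 fell (25 and 0 adjusted over the list alone), with a median of 0.90 (camera adjusted p = 2.45e-05; adjusted p = 0.781 with an estimated correlation). ERB1 rose by 2.01 (SE 0.27) and SAS10 by 1.61 (SE 0.35). The mean log2 level of this list differed between cultures of one group: relative to the untreated mean it was -0.68, 0.28 and 0.41 in untreated cultures 1 to 3 and 1.45, 0.81 and 0.53 in treated cultures 1 to 3. The number of changed members was 7 with batch as a block, 14 without untreated culture 2 and 9 without treated culture 1. In the list of 73 cytosolic ribosomal protein genes, which was drawn by name, 1 rose (RPP1, 2.23, SE 0.42) and 1 fell (RPS26A, -0.42, SE 0.14), and adjusted over the list alone 0 and 0 (camera adjusted p = 0.987). RPP1 is the name of a ribonuclease P subunit gene, so the rise is not that of a ribosomal protein. Without untreated culture 1, 11 of them changed, while 1 did so with batch as a block and without each other culture; RPS26A lost its call in those fits, with values from -0.46 to -0.37 in the latter, and also with total-count scaling (-0.25).

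**Figure D2:**
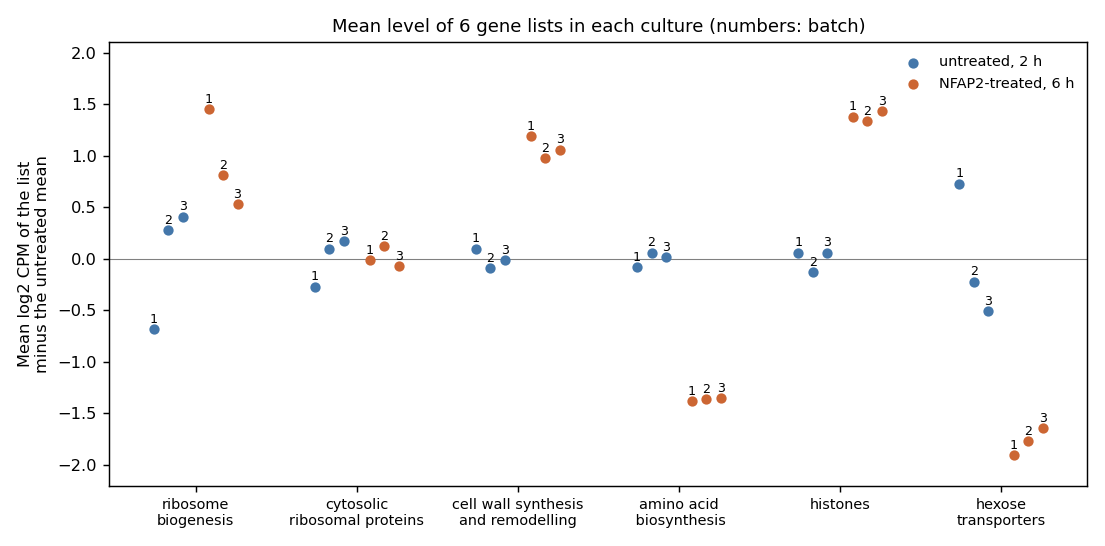
Mean log2 CPM of 6 gene lists in each culture, minus the mean of the untreated cultures, for untreated (blue, 2 h) and NFAP2-treated (orange, 6 h) cultures; the number at each point is its batch. Cell wall, histone and amino acid lists were tight within groups, while ribosome biogenesis ran from -0.68 to 0.41 in untreated and from 0.53 to 1.45 in treated cultures.

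Most glycolysis and hexose transporter genes fell. Of 21 genes of glycolysis and fermentation, 16 fell and 1 rose (17 and 2 adjusted over the list alone), with a median of -1.31 (camera adjusted p = 5.51e-07; adjusted p = 0.377 with an estimated correlation). The phosphofructokinase gene PFK2 fell from 4830 ± 308 to 937 ± 118 CPM (log2 -2.37, SE 0.15), the alcohol dehydrogenase gene ADH1 from 8564 ± 518 to 1981 ± 635 CPM (-2.11, SE 0.23), and the hexokinase gene HXK2 was at -2.11 (SE 0.16). Of 17 hexose transporter genes, 11 fell and 2 rose, also adjusted over the list alone, with a median of -1.70 (camera adjusted p = 0.00053; adjusted p = 0.485 with an estimated correlation). This list was highest in untreated culture 1, at 0.73 against -0.22 and -0.51 in untreated cultures 2 and 3, and between -1.90 and -1.64 in treated cultures. HXT5, of the same family, rose by 1.65 (SE 0.17).

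Some genes that serve growth on carbon sources other than sugar fell as well. Of 28 genes of the glyoxylate cycle, gluconeogenesis and beta-oxidation, 11 fell and 2 rose (12 and 4 adjusted over the list alone), with a median of -0.81 (camera adjusted p = 0.00472; adjusted p = 0.679 with an estimated correlation). PCK1, which encodes the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, fell from 2050 ± 236 to 90.3 ± 39.0 CPM (log2 -4.50, SE 0.32), and the peroxisome biogenesis gene PEX4 was at -3.51 (SE 0.24). Without untreated culture 1 the camera adjusted p of this list was 0.0502, and 8 members changed with batch as a block or without treated culture 1. Of 38 nuclear genes of the respiratory chain, 8 fell and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 0.144; adjusted p = 0.794 with an estimated correlation). The list was called without treated culture 3 (0.0179) and with limma-voom (0.0301), and 5 members changed with batch as a block, 4 without treated culture 1 and 4 without treated culture 2. With total-count scaling 5 fell and 1 rose. The alternative oxidase gene AOX2 was at -3.57 (SE 0.68), and at -4.95 without treated culture 3. Of 18 TCA cycle genes, 4 fell, SDH2 (-1.15, SE 0.17) among them, and 1 rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.808). The number changed was 3 with batch as a block or without treated culture 1 or 3, and 2 without treated culture 2.

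Most amino acid synthesis genes fell. Of 54 members, 47 fell, 1 rose and 6 did not pass (48 and 1 adjusted over the list alone), with a median of -1.31 (camera adjusted p = 1.56e-19; adjusted p = 0.129 with an estimated correlation). Beside LEU1, the leucine synthesis gene LEU2 fell from 709 ± 223 to 62.8 ± 17.1 CPM (log2 -3.50, SE 0.31) and LEU42 was at -2.81 (SE 0.23). The list mean lay between -1.38 and -1.35 in the treated cultures, relative to the untreated mean. Of 38 genes of nitrogen uptake and catabolism, 24 fell and 4 rose (24 and 5 adjusted over the list alone), with a median of -1.07 (camera adjusted p = 8.22e-07; adjusted p = 0.238 with an estimated correlation). The peptide transporter gene OPT2 was at -3.96 (SE 0.23) and the amino acid permease gene GAP2 at -4.55 (SE 0.54), or -3.78 without untreated culture 1, while UGA1 of GABA breakdown rose by 2.40 (SE 0.43). The rises in this list were 2 with batch as a block, 1 without untreated culture 2, and 2 without untreated culture 3 or treated culture 2 or 3. Of 20 sulfur assimilation genes, 11 fell and 1 rose, also adjusted over the list alone, with a median of -0.51 (camera adjusted p = 0.00956; adjusted p = 0.377 with an estimated correlation). MET2 of methionine synthesis was at -1.85 (SE 0.15), and the gene that rose was CYS3 (1.12, SE 0.27). Of 15 purine synthesis genes, 12 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -0.83 (camera adjusted p = 0.000272; adjusted p = 0.377 with an estimated correlation). The serine hydroxymethyltransferase gene SHM2 was at -2.79 (SE 0.23) and ADE13 at -2.33 (SE 0.25). SHM2, GCV1, GCV2 and GCV3, in this list, do not encode steps of the purine pathway itself.

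Most heat shock, osmotic and trehalose genes fell. Of 21 heat shock protein and chaperone genes, 15 fell and 1 rose, also adjusted over the list alone, with a median of -0.94 (camera adjusted p = 8.3e-05; adjusted p = 0.377 with an estimated correlation). HSP104, a disaggregase gene, fell from 1371 ± 339 to 193 ± 94.5 CPM (log2 -2.83, SE 0.36) and HSP70 from 2311 ± 632 to 361 ± 145 CPM (-2.68, SE 0.33). Of 12 osmotic and glycerol genes, 7 fell and 1 rose (7 and 2 adjusted over the list alone), with a median of -1.30 (camera adjusted p = 0.00259; adjusted p = 0.377 with an estimated correlation). The glycerol phosphatase gene RHR2 was at -2.93 (SE 0.30), and PBS2, the kinase gene upstream of Hog1, rose by 0.60 (SE 0.14). Of 11 trehalose and glycogen genes, 6 fell and 1 rose (6 and 2 adjusted over the list alone), with a median of -0.66 (camera adjusted p = 0.0149; adjusted p = 0.679 with an estimated correlation). TPS2 of trehalose synthesis was at -2.30 (SE 0.22), and without untreated culture 1 this list had a camera adjusted p of 0.0624.

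Of 27 proteasome genes, 7 fell and 0 rose, also adjusted over the list alone, with a median of -0.40 (camera adjusted p = 0.0339; adjusted p = 0.794 with an estimated correlation). RPN4, which encodes the regulator of proteasome genes, fell from 438 ± 54.0 to 219 ± 40.4 CPM (SD, n = 3 per group). The proteasome call was lost without untreated culture 1 (0.17) and without treated culture 2 (0.0509, 2 genes changed), and 4 genes changed with batch as a block, with total-count scaling or without treated culture 1. Of 33 oxidative stress genes, 7 fell and 4 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.47), with YHB1 and the peroxidase gene GPX2 (-2.77, SE 0.27) among the falls. With batch as a block 7 of them fell and 0 rose, and with total-count scaling 7 fell and 10 rose. The rises numbered 8 without untreated culture 1, 1 without untreated culture 2 or 3 and 2 without treated culture 1 or 3. Of 11 genes of autophagy and vacuolar proteases, 5 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.538): the vacuolar protease gene PRB1 was at -1.97 (SE 0.28) and the carboxypeptidase gene PRC2 rose by 2.31 (SE 0.29). Without untreated culture 1, 5 of these rose and 4 fell, and without treated culture 1 or 2, 1 rose and 3 fell. Of 12 vacuolar H+-ATPase genes, 1 passed in either count (VPH1, -0.88, SE 0.18; camera adjusted p = 0.541), and 2 did without untreated culture 1 or 3 or with the first count file alone.

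Zinc and copper genes fell or did not pass, and iron genes went both ways. Of 12 zinc and copper genes, 8 fell and 0 rose, also adjusted over the list alone, with a median of -0.91 (camera adjusted p = 0.00389; adjusted p = 0.238 with an estimated correlation), and 5 fell with the second count file alone. The copper transporter gene CRP1 fell from 2642 ± 1125 to 224 ± 29.5 CPM (log2 -3.56, SE 0.36), CSR1, the zinc regulator gene, was at -2.47 (SE 0.29) and the zinc transporter gene ZRT2 at -2.45 (SE 0.42). Of 24 iron uptake genes, 5 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.876), and with batch as a block 3 rose and 4 fell. Multicopper oxidase genes were found in both directions, FET31 at 1.77 (SE 0.18) and FET99 at -2.39 (SE 0.55).

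The other lists were mixed. Of 21 drug efflux genes, 6 rose and 5 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.808): RTA2, a membrane protein gene linked to azole tolerance, rose from 129 ± 5.91 to 1503 ± 146 CPM (log2 3.54, SE 0.15), and the ABC transporter gene CDR4 fell from 750 ± 200 to 77.1 ± 31.6 CPM (-3.28, SE 0.36). With batch as a block or the second count file alone, 3 efflux genes rose and 5 fell. Of 21 hypha-associated genes, 5 rose and 5 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.484), with the secreted protein gene RBT4 at 3.90 (SE 0.25) and the regulator genes TEC1 and BRG1 at -2.78 (SE 0.42) and -2.61 (SE 0.25). The falls in this list were 3 with batch as a block, with total-count scaling and without treated culture 1 or 2, and 8 without treated culture 3. Of 10 opaque- and white-phase markers, 1 rose (WH11) and 3 fell, also adjusted over the list alone (camera adjusted p = 0.746), and 2 in all changed with the second count file alone. Of 14 cAMP and Ras genes, 5 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.182), and RAS2 fell from 83.7 ± 3.32 to 20.9 ± 4.13 CPM (SD, n = 3 per group). CAP1 (-1.02, SE 0.13), in this list, encodes an AP-1-type factor of the oxidative stress response. The signs of the median, the mean and the test were not all alike in the iron, TCA, ribosomal protein, oxidative, drug efflux, hypha and phase lists, so no direction is given for these.

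**Figure D3:**
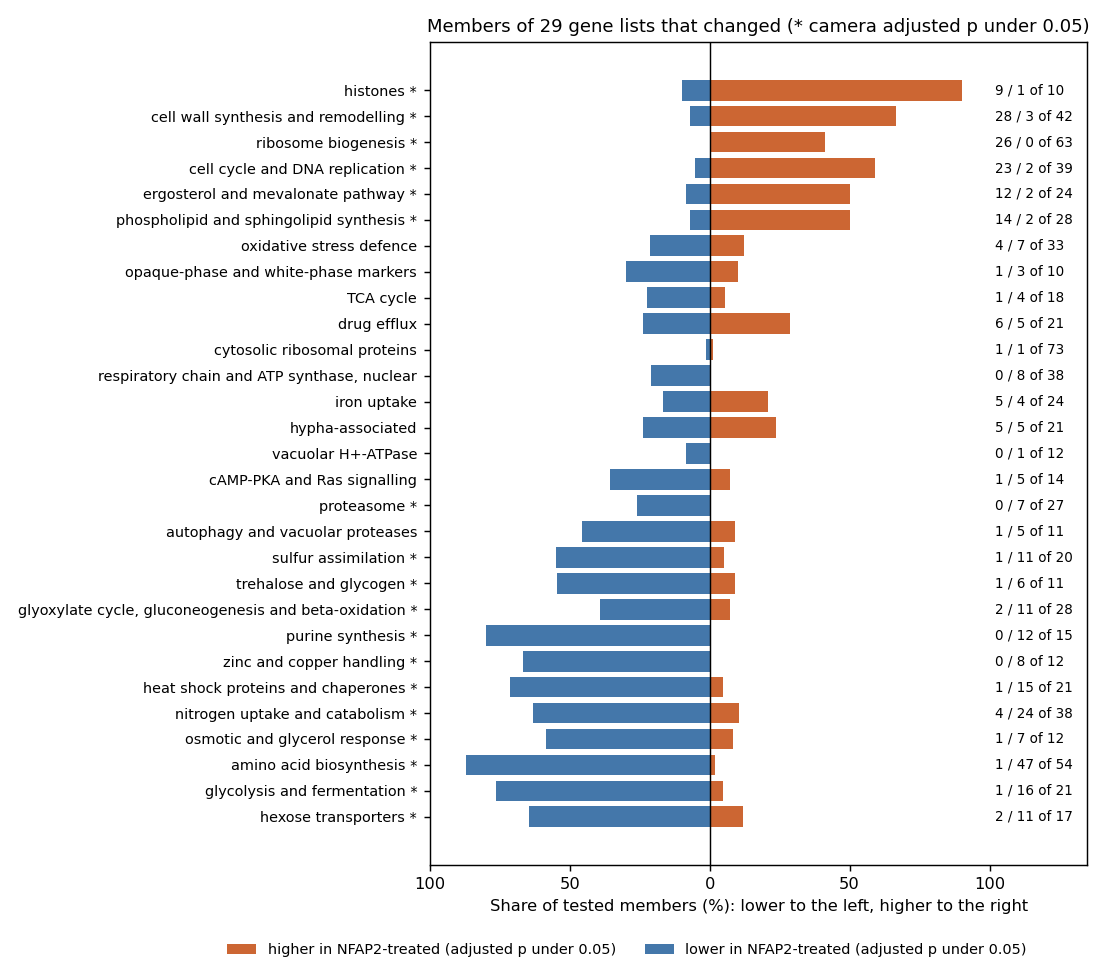
Share of the tested members of each of 29 gene lists (percent, horizontal axis) that were higher (orange, right) or lower (blue, left) in NFAP2-treated cultures at an edgeR adjusted p under 0.05, ordered by median log2 fold change; numbers at the right are members higher / lower of those tested, and asterisks mark a camera adjusted p under 0.05. The histone list had 9 of 10 members higher and the amino acid list 47 of 54 lower; with an estimated correlation 0 lists were called.

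Camera called 18 of 29 lists with its preset correlation, 6 upward and 12 downward, and 0 with a correlation estimated from these 6 cultures, where the lowest adjusted p was 0.129 and 6 lists had an unadjusted p under 0.05. Nothing in the labels beyond the batch numbers says that the cultures were grown separately, so p-values measure only the spread between these samples, which may be technical.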

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

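The direction of change was kept more often than the call. With batch as a replicate block 1799 genes changed, 1165 of them at least 2-fold, and 1790 of these 1799 had been called without the block. Beyond those named beside their results, the block changed no call of a list, and 14 of the 130 named genes lost their call. The count of changed genes was 2492 with RLE factors, 2618 with total-count scaling, 2482 without a filter, 2453 with the stricter filter, 2334 and 2060 with the first and the second count file, 3405 with the 12 files as separate samples, 2486 with limma-voom and 2482 with DESeq2. The rise to 3405 comes with counting each culture as 2 samples, and in that fit 51 ribosome biogenesis, 22 proteasome, 20 glyoxylate-list, 17 oxidative, 15 ribosomal protein, 14 respiratory, 10 cAMP and 3 V-ATPase genes changed. Leaving out 1 culture gave 1835 to 2587 changed genes, 1138 to 1395 of them at least 2-fold, and 14 to 18 called lists. Of the 2483 genes, 0 were called in the opposite direction in any of these fits. Among the named genes, 37 calls over the fits with 6 cultures or 12 files and 69 over the fits with 1 culture left out were lost, each with its sign kept. Among lists that camera did not call, the sign of the test turned in 6 and 10 cases over the same fits. With a correlation estimated for each list, 0 lists were called in place of 18, including lists with a low estimate (0.00347 for phospholipid and sphingolipid genes). That form of camera also takes its degrees of freedom from the cultures and not from the number of genes. For the phospholipid and sphingolipid list the estimate was below the preset of 0.01, so its own correlation did not end its call. For the other lists, which of the changes ended the calls was not tested. The counts between paired files differed by at most 1.055 per degree of freedom, or 1.057 over genes with at least 100 counts. Of genes changed 1.5-fold in simulated data of this comparison with 5656 genes, 18% were recovered. Far fewer genes changed in the simulation, so this share does not carry over to the real comparison. What depth and what the spread between cultures contribute was not tested.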

Other observations

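In this part, the gene groups beyond the 29 lists and the tests of explanations and splits were chosen after results had been seen. Camera values of the 29 lists given here come from the planned tests. Of 35 mannosyltransferase genes, taken by name from the PMT, MNT, MNN, KTR, BMT and OCH families, 21 rose and 4 fell, with a median log2 fold change of 0.95 (camera adjusted p = 0.000162 over 6 lists chosen after seeing the data; adjusted p = 0.207 with an estimated correlation). These enzymes build the mannan and O-linked glycans of wall proteins. KTR4 rose from 30.5 ± 3.40 to 225 ± 54.1 CPM (SD, n = 3; log2 2.88, SE 0.22), MNN15 by 1.79 (SE 0.21) and the O-mannosylation gene PMT2 by 1.39 (SE 0.19), while MNN22 fell by 2.52 (SE 0.26). The PGA family of putative GPI-anchored proteins was mixed, with 12 of 35 higher and 7 lower (camera adjusted p = 0.0693; adjusted p = 0.207 with an estimated correlation). It was called without untreated culture 2 (0.0438) and without treated culture 2 (0.0426). PGA62 rose from 805 ± 108 to 3292 ± 398 CPM (log2 2.03, SE 0.17) and PGA37 fell by 1.76 (SE 0.27).

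Of 20 genes named PHO or GIT, many of which serve phosphate and glycerophosphodiester uptake, 11 fell and 1 rose, with a median of -1.58 (camera adjusted p = 1.51e-05; adjusted p = 0.175 with an estimated correlation). Beside PHO100 and GIT4, GIT3 fell from 672 ± 209 to 77.7 ± 28.9 CPM (SD, n = 3; log2 -3.11, SE 0.34), PHO113 was at -3.82 (SE 0.34) and the phosphate transporter gene PHO84 at -2.41 (SE 0.56). The galactose genes GAL1, GAL7 and GAL10 were at -4.16 (SE 0.29), -3.75 (SE 0.20) and -4.25 (SE 0.28), in a medium whose labelled sugar is glucose. GAL102 was at -2.36 (SE 0.45). The signs of these medians were the same with RLE and total-count scaling and without each culture, except that of the PGA family, which was 0.02 and fell below 0 without untreated culture 1 or 3 and without each treated culture.

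The first pattern is that the lists called lower after 6 h with NFAP2 than after 2 h without included amino acid synthesis, glycolysis, hexose transporters and heat shock proteins, while the oxidative stress and iron lists were not called; with an estimated correlation the 4 lists named had adjusted p = 0.129, 0.377, 0.485 and 0.377, and 0 lists were called. Carbon depletion over the longer incubation would raise the glyoxylate, gluconeogenesis and beta-oxidation genes, but their median was -0.81 (95% bootstrap interval over genes, which are not independent, -1.04 to -0.51). This median was known when the prediction was written, so it is no independent test. The list had a camera adjusted p of 0.679 with an estimated correlation, and it lost its call without untreated culture 1. The values show only that these genes did not rise as a set. A more acidic medium may account for part: the median of 9 alkaline-associated genes was -0.92 (interval -1.77 to -0.17) with 5 lower and 0 higher. It was 3 lower with total-count scaling, without untreated culture 2, or without treated culture 2 or 3, and 5 lower and 1 higher without untreated culture 1. Camera did not call this list (adjusted p = 0.0899, or 0.207 with an estimated correlation). Its members PRA1, ZRT1, CTR1, FRP1, SIT1, PHO84 and PHO89 are also in the zinc and copper, iron or PHO lists. The list is thus not independent of the nutrient genes and cannot separate acidity from their fall. Of 3 acid-associated genes 2 were higher, the wall genes PHR2 at 2.04 (SE 0.16) and RBR1 at 7.41 (SE 0.36, adjusted p = 3.35e-05). Among the alkaline-associated genes, RIM101 was at -1.31 (SE 0.31, adjusted p = 0.0113), but PHR1, the counterpart of PHR2, was at -0.17 (SE 0.90, adjusted p = 0.889). PHR1 spread widely over the untreated cultures (194 ± 267 CPM, SD, against 172 ± 37.7 CPM in treated ones), so its change is not well determined. RIM8, the third acid-associated gene, was at 0.63 (SE 0.27, adjusted p = 0.0902) and passed with total-count scaling and without untreated culture 1. The prediction asked for RIM8 past the threshold, so the test decided nothing. Incubation time itself and NFAP2 cannot be told apart, since 0 samples were treated for 2 h or left untreated for 6 h.

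The second pattern is that 23 of 39 cell cycle genes rose after 6 h with NFAP2, while 2 fell and 14 did not pass (camera adjusted p = 3.68e-06; adjusted p = 0.421 with an estimated correlation). A larger share of cells at G1/S may account for it: the mean log2 fold change of 15 G1/S genes exceeded that of 12 G2/M genes by 0.75 (two-sided permutation test over genes, which are not independent, p = 0.0162), with medians of 1.08 and 0.28. The G1/S genes CDC6, CDC45, POL1, POL30, RFA1, RFA2, RNR1, CDC21 and SWI4 are also in the cell cycle list. The same holds for the G2/M genes CLB2, CLB4, CDC5 and CDC20. The comparison is thus not independent of the pattern, and it shows only that the G1/S genes rose more on average. More dividing cells stay open as well, since the G2/M median of 0.28 had an interval of -0.09 to 0.82. The G2/M genes went both ways, with CLB4 at 1.99 (SE 0.21) and IQG1 at -0.69 (SE 0.16). Effects of NFAP2 and of the longer incubation on the cycle were not separable here.

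The third pattern is that treated culture 3 lay closer to the untreated cultures than treated culture 1 did, with correlations across genes of 0.839, 0.864 and 0.873 against 0.78, 0.835 and 0.849; untreated culture 1 in turn stood apart in its group (0.956 and 0.943 against 0.989) and deviated from its group mean together with treated culture 3 (0.398). Untreated cells or RNA mixed into it would raise every fallen gene by 1 share of the untreated level. The 21 genes that were lower by 16-fold or more in treated cultures 1 and 2 needed a median share of 1.28% (95% bootstrap interval 0.69 to 2.2), and the 343 genes lower by 2 to 8-fold needed 5.4% (interval 4 to 6.62). These shares were taken against the mean of the 3 untreated cultures. The unequal shares argue against mixing at that mean level as the whole cause. The bound of 2.2% belongs to a median over genes and is not a limit on the mixed share. TNA1, at 1.71 CPM in treated culture 3 against an untreated mean of 654 CPM, left room for less than that. Mixing from a single untreated culture was not tested, and these cultures differed in some fallen genes (HGT1 at 3649, 642 and 252 CPM). TNA1, however, was at 624, 777 and 560 CPM in untreated cultures 1 to 3, which leaves room for only a small share from any of them. Whether such a share would account for part of the pattern was not tested. A weaker or slower response in treated culture 3 was not tested.

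The 6 cultures allow 10 splits into groups of 3, and 1 of the 10, the real one, gave 2483 changed genes, while the highest of the others gave 0 with edgeR. Each other split puts treated and untreated cultures in the same group. Their difference then adds to the spread within groups, so few calls can result and the contrast with 0 says nothing about chance. With 10 splits the share can never lie under 0.05.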
